A study of Mus musculus with 22 samples.

How the data were processed

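Brain endothelial cells of mice were profiled by paired-end RNA sequencing (reads of 100 bases, HiSeq4000 instrument) after sorting for CD31, per the labels' protocols. There were 22 libraries: activation (4), activation control (4), silencing (4), silencing control (4), whisker-plus (3) and whisker-minus (3). Groups and replicate numbers were taken from the sample titles. The labels call the samples biological samples, and each whisker sample pooled 5 pairs of barrel cortices.

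The authors deposited a table of CPM values for 37991 genes in the 22 libraries, with their own log2 fold changes, p-values and FDR values for each comparison, per the file headers. The submitters' processing notes name TopHat2 2.0.11, Bowtie2 2.2.1, SAMtools 0.1.19, HTSeq 0.6.1, DESeq2 and the genome build mm9, without saying what each was used for. The settings of the read counting, strand handling included, are not given in the sources used here. Genes that overlap others or have near-identical copies can therefore share reads, which applies to the globin genes and to Nr1d1, whose end overlaps Thra on the other strand. Each CPM column had the same total, and 100% of its values were whole multiples of its smallest value above 0, within 0.01 read. This gave back the whole reads, 18387666 to 57673270 per library. Depth differed between the experiments and little between the groups compared. Mitochondrial genes held 1.08 to 1.42% of reads. The columns of group means that the authors added were not used. A header states that the authors' calls have an unadjusted p under 0.05 and a mean over 10 CPM, but 2 activation calls and 4 silencing calls have a p of 0.05 or more. The authors' list of opposite changes holds 243 genes, as many as their table calls in opposite directions, but the members were not compared. How their list of barrier genes was chosen is not given in the sources used here, and it may hold genes picked from these libraries.

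Gene names were those of the table, with 25 names restored that had turned into dates. Of the gene identifiers 86.6% were found in GENCODE M21. That annotation belongs to another build than mm9, so it served only for names and gene types, and no coordinates are given. The table holds 3750 entries that share a symbol with another.

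The design fixed before the data were examined named edgeR for raw counts and limma for any other unit. As the table holds CPM, limma 3.58.1 in R 4.3.3 was used, with a mean-variance trend, on log2(CPM + 1). Genes with at least 1 CPM in as many libraries as the smaller group were tested, with no scaling beyond CPM. The median log2 fold change of all tested genes was then -0.0072 for activation, -0.073 for silencing, -0.068 for whisker and 0.059 for the difference of effects. Counts of list members above or below 0 should be read beside these medians, which lay nearer 0 with RLE or TMM scaling. Each comparison used only its own groups, and the difference of the activation and silencing effects used the 16 DREADD libraries. A fold change on this scale understates the change of low genes. Calls had a Benjamini-Hochberg adjusted p under 0.05. Alternatives were RLE and TMM scaling, no filter, a pseudocount of 0.1, a fit of all 22 libraries, leaving out each library, DESeq2 1.42.0, and edgeR 4.0.16 with its quasi-likelihood test on the recovered reads. TMM scaling, edgeR, the fit of all 22 libraries for the difference of effects and all settings combined with the replicate block were added after seeing the data. The count tests on recovered reads called 2 (edgeR) and 371 (DESeq2) genes for activation, 24 and 462 for silencing, 0 and 406 for whisker, and 295 and 760 for the difference of effects.

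Replicate numbers are shared between the compared groups in the titles, and no label says what a number stands for. The deviations of same-numbered libraries from their group means had correlations of 0.37, 0.45, 0.43 and 0.28 in the activation experiment, 0.60, 0.16, 0.44 and 0.14 in the silencing experiment and 0.46, 0.48 and 0.62 in the whisker experiment. Each of the 8, 8 and 6 libraries lay closest to the one of its own number in the other group. The libraries were therefore taken as paired, on the evidence of the data and not of the design. These correlations and the counts of calls were first seen together. The fit with the number as a replicate block stands beside the unblocked one wherever it changes a call or moves a count by over 1.5 times.

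Lists of genes (38, of pathways, barrier functions and cell type markers) were fixed before the data were examined. They were tested with camera at its preset correlation of 0.01, over lists with at least 3 tested genes, and again with an estimated correlation. Named genes follow a rule fixed at the same time. It takes the 8 rising and 8 falling genes with the largest change among genes that passed, with a mean of at least 5 CPM and every treated library beyond every control, or the 4 with the smallest p per direction where none passed. It adds up to 4 members per list that passed, a panel of transporter, clock and barrier genes, and 8 shared genes per overlap, and leaves out pseudogenes and predicted genes. Applying it to the fit with the block as well was decided after seeing the data. Genes of smaller interest, such as Wdr60, Per3 and Cry1, are named where a count is small, after their values were seen.

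Every fit was tested on simulated counts with 200 changed genes outside the lists, in a single draw per comparison. The ribosomal protein genes were also raised 1.5-fold. They count as true calls in the percent of false calls and are left out of the recovery values. Means, dispersions and depths came from the real libraries as fitted with the replicate block. Differences between pairs were thus built into the simulated counts. The higher recovery with the block below follows from that and is no evidence that the libraries are paired. For activation (12664 genes) limma found 13.4% of genes changed 1.5-fold, 59.1% of those changed 2-fold and 92.3% of those changed 4-fold, with 0.877% false calls, and with the replicate block 53.7%, 80.3% and 100%, with 8.12% false. For silencing (12901 genes) it found 14.9%, 71.2% and 100%, with 0% false, and with the block 46.3%, 87.9% and 100%, with 6.49% false. For whisker (12620 genes) it found 7.81%, 39.4% and 86.4%, with 0% false, and with the block 56.2%, 75.8% and 97%, with 10.6% false. For the difference of effects (13347 genes) the values were 1.49%, 39.4% and 70.8%, with 0% false, and with the block 14.9%, 59.1% and 84.6%, with 4.24% false. The block thus let through more false calls than the threshold of 5% in 3 of the 4 simulations. Simulated genes vary independently, which real ones do not. Within each group no pair of libraries was a duplicate: the chi-square per gene between them was 18.2 to 135.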

Results

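RNA was sequenced from endothelial cells, the lining cells of blood vessels that form the blood-brain barrier, taken from mice whose neural activity had been altered. Cells carrying the endothelial surface protein CD31 were enriched by fluorescence-activated sorting. In the first experiments, glutamatergic neurons were addressed with DREADDs, designer receptors that respond to the drug CNO. The receptor hM3Dq excites neurons and gave the activation group (4 libraries), and hM4Di inhibits them and gave the silencing group (4 libraries). Each had its own littermate control group of 4 libraries, and cortex and hippocampus were collected 3 hours after CNO. The series text says that the controls carried no DREADD, while the genotype label of each control group is that of its treated group. In the whisker experiment, wild-type mice explored a newly enriched cage in the dark with their whiskers (whisker-plus, 3 libraries), and mice without whiskers stayed in an empty cage (whisker-minus, 3 libraries). Each of these libraries pooled 5 pairs of barrel cortices, so whiskers and environment differed together. Depth was 18387666 to 25163689 reads per library in the activation experiment, 25897142 to 32957916 in the silencing experiment and 44187482 to 57673270 in the whisker experiment. Values are CPM, the reads of a gene scaled to a common library total, given as mean ± SD with n = 4 per DREADD group and n = 3 per whisker group. Log2 fold changes are on the log2(CPM + 1) scale with their standard error (SE), and adjusted p-values are those of limma unless another tool is named. A gene called with the replicate block is one that passed when libraries of the same number were compared as pairs.

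The activation comparison asked how endothelial transcripts differed after excitation of glutamatergic neurons. Mcam (ENSMUSG00000032135), an endothelial adhesion molecule, rose to 172 ± 33.8 CPM against 68.6 ± 15.2 in controls, a log2 fold change of 1.32 ± 0.18 (adjusted p = 0.041). Mall, a membrane raft protein, rose to 122 ± 16.9 CPM against 56.7 ± 12.2 (log2 1.10 ± 0.15, adjusted p = 0.0418). The other rising genes that met the naming rule had log2 fold changes of 1.15 ± 0.18 for the tetraspanin Tspan2, 0.93 ± 0.14 for the growth factor Pdgfa, 0.84 ± 0.14 for the Src-family kinase Fyn, 0.71 ± 0.11 for Pdlim5 and 0.64 ± 0.10 for the actin-bundling protein Pls3. Igf1r (ENSMUSG00000005533), the receptor of insulin-like growth factor, fell to 262 ± 21.4 CPM against 494 ± 98 (log2 -0.89 ± 0.14, adjusted p = 0.0495), and Vwf, the clotting protein stored in endothelial granules, fell to 417 ± 46.8 CPM against 658 ± 43.5 (log2 -0.66 ± 0.11, adjusted p = 0.0495). Akr1e1, an aldo-keto reductase, fell by 1.49 on the log2 scale, to 3.38 ± 0.448 CPM against 11.6 ± 3.24. The other falling genes were Phactr1 (-0.88 ± 0.11), Myof (-0.83 ± 0.11), Megf6 (-0.83 ± 0.12), Pcnt (-0.70 ± 0.09) and Tgfbr3 (-0.69 ± 0.11), a co-receptor of TGF-beta. In each gene named here all 4 activation libraries lay beyond all 4 controls. In total 18 of 12872 tested genes passed an adjusted p of 0.05, 9 rising and 9 falling. With the replicate block 234 genes passed (132 rising, 102 falling), all 18 among them. The 18 rest on the setting: 0 passed with RLE or TMM scaling or no filter on low values (1470 at an unadjusted p under 0.05 as fitted), and edgeR called 2 and DESeq2 371. With 1 library left out 0 to 8 passed (8 without activation control 2, 2 without activation control 1 and 0 without any other), and with the block 5 to 50 with a pair left out and 0 with no filter. The authors' deposited table marks 1372 genes, by a stated rule of an unadjusted p under 0.05 and a mean over 10 CPM. In the authors' deposited table a p of 0.05 or more stands beside 2 of these marks and 2 go against the sign of the fold change, and 322 genes in it have an FDR under 0.05.

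Pairing libraries by number brought in more genes. Adamts9, a matrix protease, rose with the replicate block to 96.9 ± 64.3 CPM against 20.6 ± 6.83 (log2 2.00 ± 0.30, adjusted p = 0.0264). So did the tubulin Tubb6 (1.74 ± 0.23), Ppm1j (1.15 ± 0.14) and the cell-cycle gene Ccnd1 (1.00 ± 0.10). Falling with the block were Ddc, which encodes aromatic amino acid decarboxylase (106 ± 30.3 CPM against 221 ± 41.3; log2 -1.08 ± 0.09, adjusted p = 0.00523), Scube2 (-0.93 ± 0.13), the PAR bZIP transcription factor Tef (-0.91 ± 0.11) and Arhgap19 (-0.87 ± 0.18). Without it none of these passed, with adjusted p-values from 0.0527 (Tef) to 0.18 (Scube2) among the falling genes. Of 38 lists fixed before the data were examined, 5 stood apart from other genes in the camera test with its preset correlation. ABC efflux transporters, which pump drugs out of endothelial cells, lay lower, with 11 of 13 members below 0 and a median log2 fold change of -0.24. Their camera adjusted p was 0.00575 (adjusted p = 0.648 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 6 fell with the replicate block when adjusted over the list alone. Abcb1a, the main P-glycoprotein gene of the barrier, stood at 1893 ± 154 CPM against 2399.8 ± 218 (log2 -0.34 ± 0.12, adjusted p = 0.32). Abcg2 stood at 760.0 ± 130.4 CPM against 919.8 ± 76.6 (-0.29 ± 0.13, adjusted p = 0.447). Abcc4 stood at 565 ± 122 CPM against 858 ± 153 (-0.61 ± 0.18, adjusted p = 0.215) and Abcb1b 0.33 ± 0.23 at a low level of 2.36 ± 1.1 CPM. Heat shock and unfolded protein genes lay higher, 22 of 25 above 0 (median 0.23, camera adjusted p = 0.00126, and adjusted p = 0.899 with an estimated correlation). None passed over all genes or adjusted over the list alone. With the block Hsp90aa1 rose (0.73 ± 0.08, adjusted p = 0.0095) and 8 did adjusted over the list alone. Caveolae and transcytosis genes had 12 of 16 members above 0 (median 0.16, camera adjusted p = 0.0126, and 0.648 as adjusted p with an estimated correlation). Adjusted over the list alone 3 passed, and with the block Prkcdbp, the gene of a caveolar coat protein (0.51 ± 0.09), and Ehd2 (0.58 ± 0.10) rose. Cholesterol synthesis genes had 16 of 21 above 0 (median 0.16, camera adjusted p = 0.0191) with 2 passing adjusted over the list alone, and extracellular matrix genes 16 of 25 (median 0.20, camera adjusted p = 0.0416) with 4. For both lists the adjusted p was 0.899 with an estimated correlation. Among matrix genes Nid1 (0.43 ± 0.08) rose and Lama3 (-0.58 ± 0.09) fell with the block. Leaving out 1 library ended the call of heat shock genes (activation control 1, adjusted p = 0.217), caveolae genes (activation control 3 or activation 1, 0.0508 and 0.0633), cholesterol genes (activation control 1, 3 or 4 or activation 3, 0.0508 to 0.12) and matrix genes (activation control 1 or 3 or activation 1 or 4, 0.0596 to 0.217). The call of matrix genes also ended with RLE, TMM or no filter (adjusted p = 0.0562, 0.0558 and 0.054). The block added angiogenesis and tip cell genes (camera adjusted p = 0.0367, 13 of 24 above 0). It also added glucocorticoid response genes (0.0479, 17 of 22 above 0, with Mt2 rising by 0.83 ± 0.15) and smooth muscle markers (0.0305, 9 of 9 above 0). With an estimated correlation these 3 had adjusted p-values of 0.746, 0.84 and 0.84. Without activation control 1, and with no block, the median of glucocorticoid genes was -0.0097 (camera adjusted p = 0.853), so that library carries their direction. TMM scaling with the block ended the calls of angiogenesis and cholesterol genes (adjusted p = 0.0653) and of glucocorticoid and matrix genes (0.0815). Tight and adherens junction genes split evenly, 10 above and 10 below 0 of 20 (camera adjusted p = 0.891).

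The circadian clock genes of the fixed panel read as follows after activation. The PAR bZIP factors were lower without passing, Dbp at 6.61 ± 1.78 CPM against 14.3 ± 6.7 (log2 -0.92 ± 0.31, adjusted p = 0.283), Tef at 45.5 ± 1.75 CPM against 88.3 ± 21.8 and Hlf at 13.7 ± 1.62 CPM against 24.7 ± 4.73 (-0.80 ± 0.15, adjusted p = 0.0896). With the replicate block Tef (adjusted p = 0.0172) and Hlf (0.0425) fell and Arntl (0.43 ± 0.09, adjusted p = 0.0466) rose. The other clock genes gave log2 fold changes of -0.04 ± 0.31 for Per1, -0.29 ± 0.45 for Per2, -0.12 ± 0.36 for Nr1d1, 0.03 ± 0.30 for Nr1d2, -0.25 ± 0.15 for Ciart (listed as Gm129) and 0.04 ± 0.14 for Clock, none passing with or without the block. Barrier and endothelial genes lay near 0: Cldn5 -0.14 ± 0.16, the glucose transporter Slc2a1 0.01 ± 0.20, the lipid transporter Mfsd2a 0.09 ± 0.13 and Pecam1, which encodes CD31, 0.07 ± 0.11. Fos read 0.06 ± 0.27 at 6707 ± 1892 CPM against 6439.6 ± 1877, and Fkbp5 0.53 ± 0.58, none passing. Of the 48 tested genes on the authors' own blood-brain barrier list 30 lay below 0, and 1 rose and 1 fell, also when adjusted over the list alone. The list lay lower in the camera test (adjusted p = 0.0382, and adjusted p = 0.104 with an estimated correlation) and did not pass with the replicate block (adjusted p = 0.0532) or with RLE or TMM scaling (0.0541 and 0.0502). It did not pass after silencing (adjusted p = 0.685, 28 of 48 below 0) or in the whisker comparison (0.83, 27 of 47 below 0). That list was drawn up for this study, so its direction is not independent evidence if these libraries guided the choice.

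**Figure D1:**
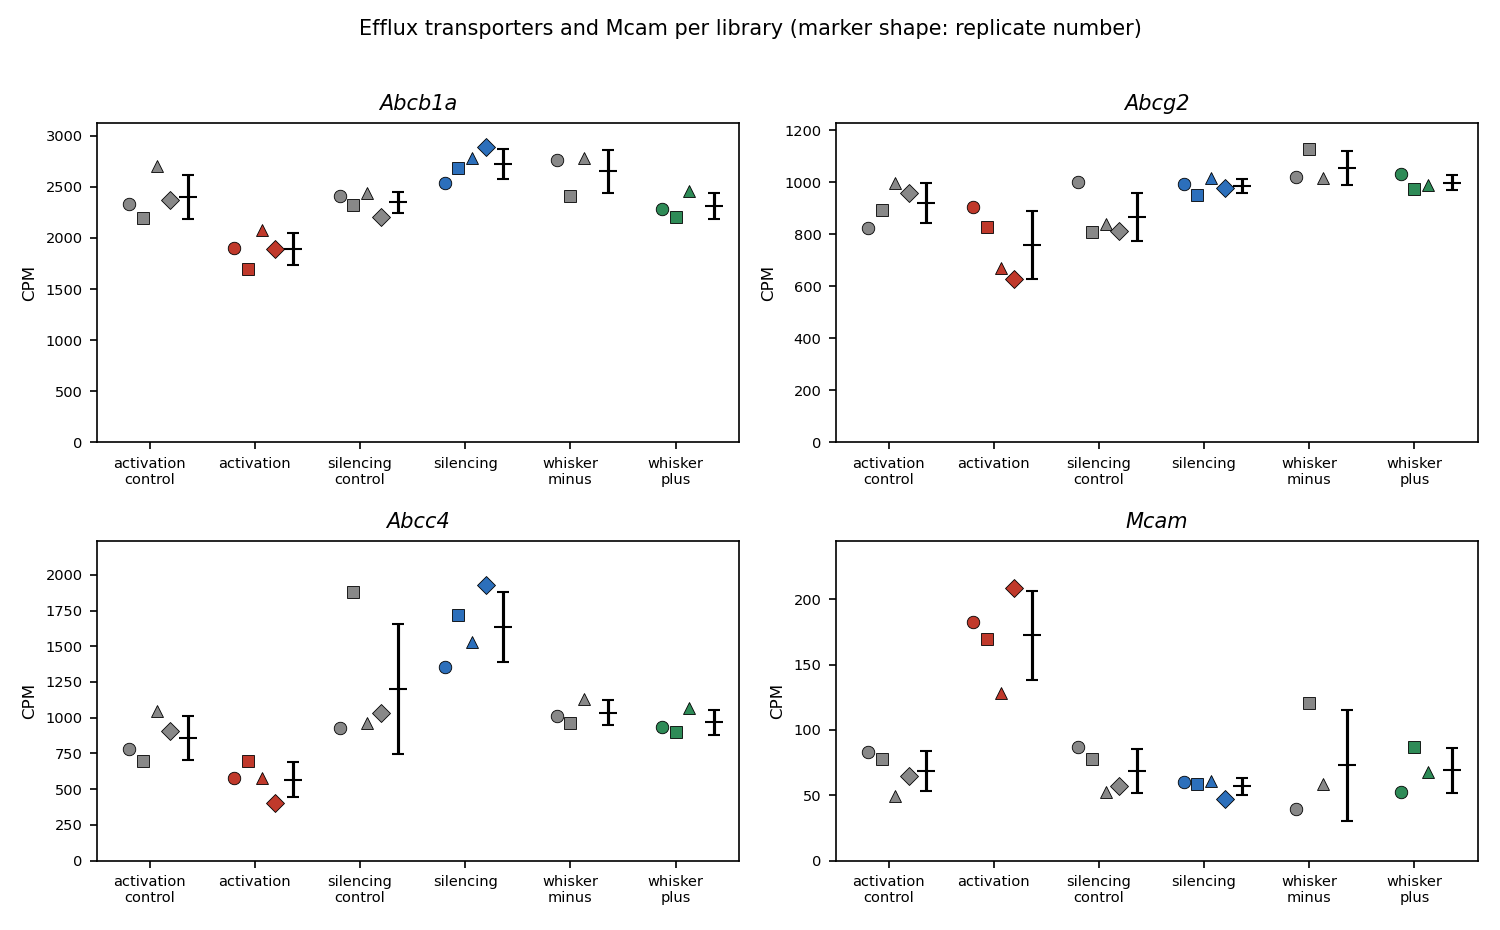
CPM per library of Abcb1a, Abcg2, Abcc4 and Mcam in the 6 groups, with points for libraries, marker shapes for replicate numbers and bars for mean ± SD. Mcam averaged 172 CPM in activation libraries against 68.6 in their controls, while the Abcc4 level of silencing control 2 (1883 CPM) stands above that of the other silencing controls.

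The silencing comparison asked the same after inhibition of glutamatergic neurons. Wnk4 (ENSMUSG00000035112), a kinase that regulates ion transport, rose to 16.8 ± 2.85 CPM against 5.09 ± 0.973 (log2 1.55 ± 0.15, adjusted p = 0.0151). Other rising genes were Zbtb8a (1.35 ± 0.17), the mitochondrial carrier Slc25a33 (1.29 ± 0.19), the Ras regulator Rasal2 (0.90 ± 0.13), Ston1 (0.88 ± 0.14), Mxd4 (0.83 ± 0.12), Tprn (0.79 ± 0.12), Acy1 (0.77 ± 0.08) and Ddc (0.59 ± 0.09). Kdr (ENSMUSG00000062960), the main VEGF receptor of endothelial cells, fell to 610.1 ± 106 CPM against 1272 ± 198 (log2 -1.06 ± 0.16, adjusted p = 0.0478). Pik3r3, a regulatory subunit of PI3-kinase (-0.85 ± 0.11), the ribosome assembly genes Urb2 (-0.83 ± 0.10) and Bysl (-0.79 ± 0.11), the glycolytic enzyme gene Tpi1 (-0.52 ± 0.07), Auts2 (-0.52 ± 0.08) and the lipid droplet gene Plin2 (-0.51 ± 0.07) fell too. Of 13017 tested genes 23 passed, 16 rising and 7 falling (29 and 6 with TMM scaling). The replicate block gave 136 (79 and 57, or 96 and 38 with TMM), all 23 among them. With the block Trp53inp1 (2.28 ± 0.39), Lao1 (1.93 ± 0.27), Lpin2 (1.67 ± 0.20), Net1 (1.56 ± 0.17) and Spsb1 (1.56 ± 0.26) rose. Falling with it were the vascular cadherin gene Pcdh12 (-1.55 ± 0.13), the lactate transporter Slc16a1 (-1.30 ± 0.17), Mmp15 (-1.15 ± 0.16), Glipr2 (-1.02 ± 0.11), Klhl6 (29.5 ± 4.16 CPM against 61.3 ± 16.4), Tnfsf10 (-0.97 ± 0.12) and the chemokine gene Cxcl12 (1658 ± 249 CPM against 3189 ± 736; log2 -0.93 ± 0.13, adjusted p = 0.0298). One library sets the count: without silencing control 2, limma called 1504 genes, the 23 included. Leaving out each of the other 7 libraries gave 0 to 13 (0 without silencing control 1 or 4 or silencing 1, 2 or 3, 7 without silencing control 3 and 13 without silencing 4). DESeq2 called 462, a pseudocount of 0.1 gave 14 and no filter gave 7. The blocked count was 2399 without pair 2, 0 without each of the other pairs and 0 with no filter. The authors' deposited table marks 1323 genes, 4 of them with a p of 0.05 or more and 1 against the sign of its fold change, and has 430 with an FDR under 0.05.

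Glucocorticoid response genes lay highest among the fixed lists after silencing, 21 of 23 above 0 with a median log2 fold change of 0.65 (camera adjusted p = 8.95e-14, and adjusted p = 0.7 with an estimated correlation). Adjusted over the list alone 13 passed, and over all genes none without the block. Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 293 ± 48.2 CPM against 131 ± 226 (log2 2.85 ± 0.95, adjusted p = 0.199), and silencing control 2 held 469 CPM of it. With the block Klf15 (23 ± 4.48 CPM against 5.32 ± 5.67; log2 2.27 ± 0.32, adjusted p = 0.029), Hif3a (2.16 ± 0.33) and Ddit4 (1.33 ± 0.13) rose. Without silencing control 2 the list median was 0.96, Fkbp5 stood at 4.03 (adjusted p = 8.8e-05) and Klf15 at 2.80. Clock output genes had 11 of 15 above 0 (median 0.49, camera adjusted p = 5.75e-05, and adjusted p = 0.897 with an estimated correlation), 3 rising and 1 falling adjusted over the list alone. Hlf read 50.5 ± 5.62 CPM against 22.4 ± 8.51 (1.21 ± 0.24), Tef 133 ± 32.9 CPM against 78.2 ± 21 (0.75 ± 0.23), Per2 1.05 ± 0.37 and Arntl -0.47 ± 0.10. With the block Hlf (adjusted p = 0.0226), Tef (0.0268) and Per2 (0.0416) rose and Arntl fell (0.039), and without silencing control 2 these 4 passed with no block (limma adjusted p = 0.00421 for Hlf to 0.0373 for Per2). Dbp 0.67 ± 0.33, Per1 0.49 ± 0.41, Nr1d1 0.33 ± 0.24, Nr1d2 0.58 ± 0.21, Ciart 0.99 ± 0.47 and Clock 0.04 ± 0.09 did not pass. All 21 cholesterol synthesis genes lay below 0 (median -0.32, camera adjusted p = 2.15e-06, and adjusted p = 0.7 with an estimated correlation), 6 passing adjusted over the list alone. Cyp51 (-0.66 ± 0.09) and Sqle (-0.68 ± 0.11), enzymes of sterol synthesis, fell with the block. Angiogenesis and tip cell genes had 21 of 24 below 0 (median -0.33, camera adjusted p = 0.0405, and adjusted p = 0.7 with an estimated correlation). Kdr passed over all genes, 6 passed adjusted over the list alone, Pdgfb (-0.49 ± 0.08) fell with the block, and the list's camera adjusted p became 0.227 without silencing control 2 and 0.073 without silencing 3. All 37 oxidative phosphorylation genes lay below 0 by a small amount (median -0.18, camera adjusted p = 0.000231, and adjusted p = 0.944 with an estimated correlation), with no member passing. The median of all tested genes was itself -0.073 after silencing, so counts of members below 0 lean that way. Markers of mural cells, which wrap vessels, were higher: 11 of 11 for pericytes (median 0.35, camera adjusted p = 0.0168) and 9 of 10 for smooth muscle (0.27, 0.0147), with no member passing. With an estimated correlation both stood at an adjusted p of 0.944. The pericyte call ended with silencing control 2, 3 or 4 or silencing 1 or 3 left out (adjusted p = 0.073 to 0.306) and that of smooth muscle without silencing control 4 or silencing 3 (0.376 and 0.073). Both calls also ended with RLE (adjusted p = 0.122 for pericytes and 0.0705 for smooth muscle) and TMM scaling (0.0856 and 0.0508), and that of smooth muscle with all 22 libraries in the fit (0.131). The block added astrocyte markers, 14 of 16 below 0 (median -0.33, camera adjusted p = 0.023). It also added neuron markers, 10 of 11 above 0 (0.15, 0.0265). Both stood at an adjusted p of 0.962 with an estimated correlation. With RLE or TMM scaling astrocyte markers were called without the block too (adjusted p = 0.0154 and 0.0194), and neuron markers were not called with it (0.0615 and 0.0525).

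Among transporters and barrier genes after silencing, Abcb1a read 2723 ± 148 CPM against 2347 ± 106 (log2 0.21 ± 0.12, adjusted p = 0.427), Abcg2 0.19 ± 0.10, Abcc4 0.50 ± 0.23 and Abcb1b -0.12 ± 0.17. Cldn5 stood at 2357 ± 308 CPM against 3970.0 ± 1405 (-0.68 ± 0.28, adjusted p = 0.273), Slc2a1 at 0.66 ± 0.28, Mfsd2a at -0.43 ± 0.12, Fos at 0.19 ± 0.24 and Pecam1 at -0.09 ± 0.12. None of these passed, with or without the replicate block. Without silencing control 2 Slc2a1 rose by 0.92 (adjusted p = 0.0106) and Abcc4 by 0.74 (adjusted p = 0.00869), while Cldn5 fell by 0.96 (adjusted p = 0.00867) and Mfsd2a fell by 0.48 (adjusted p = 0.0309).

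**Figure D2:**
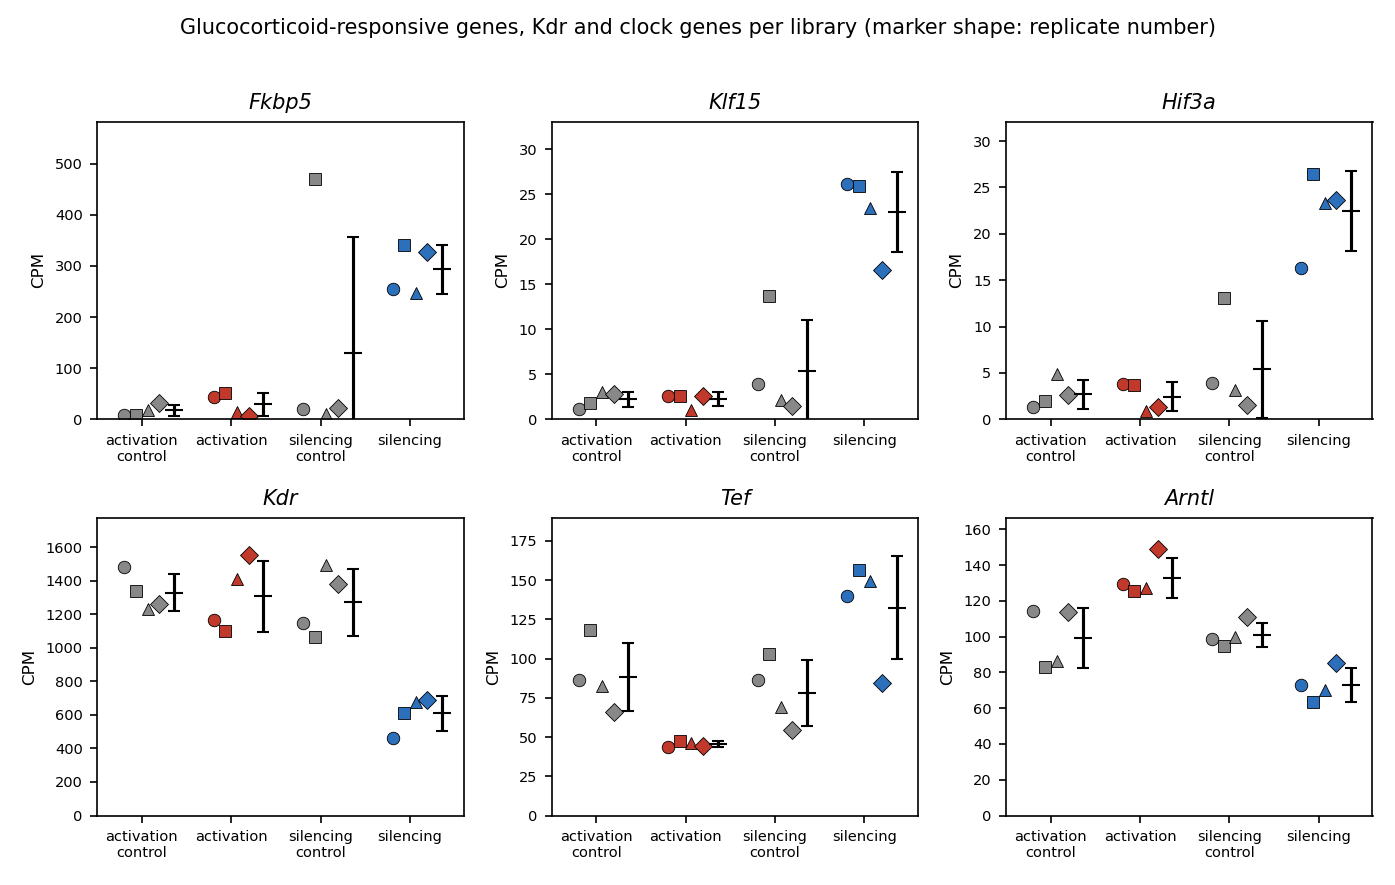
CPM per library of Fkbp5, Klf15, Hif3a, Kdr, Tef and Arntl in the 4 DREADD groups, with points for libraries, marker shapes for replicate numbers and bars for mean ± SD, ended at 0 where the lower bar would pass it. Silencing control 2 holds 469 CPM of Fkbp5, against a silencing mean of 293, while its Kdr level of 1068 CPM lies with the other controls.

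The difference between the activation and silencing effects was tested gene by gene over the 16 DREADD libraries. It passed in 311 of 13464 genes, 196 with a more positive effect of activation and 115 with a more positive effect of silencing, and in 855 with the replicate block (541 and 314). Ddc differed towards silencing (-1.67 ± 0.23, adjusted p = 0.00296), and Islr2 (-2.55 ± 0.50), Klf15 (-2.26 ± 0.57), Klhl3 (-2.10 ± 0.35), Hlf (-2.01 ± 0.30), Wnk4 (-1.90 ± 0.28), Net1 (-1.75 ± 0.35), Lpin2 (-1.73 ± 0.42) and Tef (-1.67 ± 0.29) did so too. Towards activation differed Tubb6 (2.45 ± 0.56), Pcdh12 (2.03 ± 0.40), Ccnd1 (1.81 ± 0.28), Mall (1.62 ± 0.26), Pdgfa (1.62 ± 0.22), Mcam (1.57 ± 0.26), Mmp15 (1.53 ± 0.28), Rin1 (1.46 ± 0.33) and Arntl (0.90 ± 0.16). Cholesterol synthesis genes had 19 of 21 above 0 (median 0.58, camera adjusted p = 2.57e-06, and adjusted p = 0.654 with an estimated correlation). Of these 5 passed, Sqle (1.36 ± 0.20), Cyp51 (1.16 ± 0.24), Hsd17b7 (0.77 ± 0.18) and the regulator Srebf2 (0.54 ± 0.13) among them, and 7 adjusted over the list alone. Angiogenesis genes had 20 of 24 above 0 (median 0.62, camera adjusted p = 0.00137, and adjusted p = 0.0891 with an estimated correlation), with Kdr (1.03 ± 0.21) and Mcam passing and 5 adjusted over the list alone. Oxidative phosphorylation genes had 37 of 38 above 0 (median 0.18, camera adjusted p = 0.00818, and adjusted p = 0.986 with an estimated correlation). This call ended without activation control 3 or 4 or silencing control 4 (adjusted p = 0.0509 to 0.152). The median of all tested genes was itself 0.059 for the difference of effects. Below 0 lay glucocorticoid genes, 17 of 23 (median -0.51, camera adjusted p = 0.000334). So did clock output genes, 11 of 15 (-0.55, 0.00137), and ABC efflux genes, 9 of 13 (-0.28, 0.00424). The adjusted p-values of these 3 were 0.836, 0.763 and 0.654 with an estimated correlation. Without the block 1 member passed among glucocorticoid genes (Klf15), 2 among clock output genes (Hlf and Tef) and 1 among efflux genes (Abca3, -0.68 ± 0.17). Adjusted over the list alone 3, 4 and 5 passed below 0, beside 1 clock gene above. Other list members that passed were Slco2a1 (-1.25 ± 0.23), Ace (-0.97 ± 0.18), Vegfa (1.06 ± 0.25), Icam2 (0.89 ± 0.22) and Eng (0.71 ± 0.18). With the block Abcc4 (-1.11 ± 0.27, adjusted p = 0.0349), Abcb1a (-0.55 ± 0.14, adjusted p = 0.0435), Dbp (-1.59 ± 0.38) and Ciart (-1.24 ± 0.25) differed as well. The block further called heat shock (camera adjusted p = 0.00512, 21 of 25 above 0), hypoxia (0.0452, 17 of 22) and astrocyte genes (0.0419, 15 of 16). These had adjusted p-values of 0.921, 0.804 and 0.944 with an estimated correlation. Among their members Hsp90aa1 (0.90 ± 0.16), Hsph1 (1.43 ± 0.27) and the glycolytic genes Aldoa (0.56 ± 0.10) and Ldha (0.97 ± 0.20) passed with the block. The balance turned with scaling, to 148 and 178 with TMM and 134 and 194 with RLE, and the blocked balance to 437 and 403 with TMM. The count was 487 without activation control 1 and 915 without silencing control 2. It was 85 (without silencing control 4) to 195 without activation control 3 or 4, activation 1, 2 or 4, silencing control 3 or 4 or any silencing library.

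No gene passed the test in both the activation and the silencing comparison, so the count of opposite changes was 0 with limma and 31 with DESeq2. At an unadjusted p under 0.05 in both, 281 genes had opposite and 53 the same direction. Paired by the replicate block, 6 genes changed in opposite directions among 12667 genes tested in both, where independent lists would share 1.21, and 1 gene, Wdr60, changed in the same direction. Tef, Hlf and Ddc fell after activation and rose after silencing (Fisher's exact test, two-sided, p = 0.0241). Conversely Arntl, the adhesion molecule gene Pvr (0.55 ± 0.08 and -0.62 ± 0.11) and Fam101b (0.58 ± 0.11 and -0.66 ± 0.11) rose after activation and fell after silencing (Fisher's exact test, two-sided, p = 0.0215). These Fisher tests treat genes as independent, which they are not, and Tef, Hlf and Arntl are all clock genes. With the block TMM scaling gave 2 and edgeR 2, all of them falling after activation and none rising, and no filter gave 0. Leaving out a pair gave 0 to 64 (64 without silencing pair 2, 0 without each other silencing pair, 1 without activation pair 1 or 3 and 3 without activation pair 4). Across genes, which are not independent replicates, the log2 fold changes of the comparisons had a Pearson r of -0.13. The authors' deposited table holds 243 genes called in opposite directions and 39 in the same direction. Their list of opposite changes, of 243 genes too, was taken as chosen on these libraries, so its direction here is not independent evidence. After activation 2 of its 242 tested genes rose and 7 fell over all genes, or 86 and 114 adjusted over the list alone. After silencing 3 rose and 1 fell, or 72 and 103. Its camera test and median after silencing lay above 0 (median 0.15, camera adjusted p = 0.000579, and adjusted p = 0.241 with an estimated correlation), while its mean lay just below 0.

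The whisker comparison asked how barrel cortex endothelium differed after whisker-guided exploration. The acute phase gene Lcn2 (ENSMUSG00000026822) stood at 72.6 ± 15.9 CPM against 11 ± 6.6 in mice without whiskers and rose with the replicate block (log2 2.77 ± 0.23, adjusted p = 0.00132; 0.18 without the block). With it rose the venular chemokine-binding receptor Darc (2.08 ± 0.16), Serpina3g (1.71 ± 0.23), Lrg1 (1.34 ± 0.17), Adamts9 (1.28 ± 0.27), the vessel growth regulator Angpt2 (1.24 ± 0.15), the chaperone Hsph1 (101 ± 11.3 CPM against 42.6 ± 7.22; 1.24 ± 0.11), Mall (1.09 ± 0.09) and Fyn (0.69 ± 0.07). The falling genes with the largest changes were expressed at low levels, Kif1a (2.68 ± 0.852 CPM against 13.2 ± 8.61; -1.71 ± 0.27), Slc25a18 (-1.70 ± 0.35), Srgap3 (-1.52 ± 0.36), Pcdh10 (-1.51 ± 0.32), Scg3 (-1.47 ± 0.27), Fads2 (-1.46 ± 0.24), Rab11fip4 (-1.45 ± 0.35) and Fam171b (-1.38 ± 0.30). Aldh4a1 (-0.79 ± 0.08), Ddc (-0.61 ± 0.06), Frmd5 (-0.72 ± 0.10) and Pcca (-0.55 ± 0.07) fell too. The first 8 were highest in whisker-minus 2 and 3, as astrocyte markers were: on the log2 scale whisker-minus 1 lay 4.93 to 26.2% of the way from the whisker-plus mean to the mean of those libraries, against 73.7 to 96% for Aldh4a1, Ddc, Frmd5 and Pcca and a median of -5.84% for 16 astrocyte markers. Without the block limma called 0 of 12776 genes, edgeR 0 and DESeq2 406, while 1656 had an unadjusted p under 0.05 and the smallest adjusted p was 0.164. With the block 1097 passed, 382 rising and 715 falling (484 and 359 with TMM scaling). Without whisker-minus 1 limma called 352 genes with no block, and with the block the count was 2381 without pair 1, 689 without pair 2 and 1 without pair 3. No filter on low values gave 0 with the block. The authors' deposited table marks 1234 genes, and 339 have an FDR under 0.05.

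Astrocyte markers had the median furthest from 0 among the 10 lists called in the whisker libraries. All 16 lay below 0, with a median of -1.17 (camera adjusted p = 1.68e-05, and adjusted p = 0.548 with an estimated correlation, a value that held for all 10 lists called). No marker passed without the block, and 10 fell with it, Slc1a3 (37 ± 6.95 CPM against 103 ± 61.6; -1.21 ± 0.28), Gja1 (-0.55 ± 0.12), Acsbg1 (-1.56 ± 0.35) and Gpr37l1 (-1.48 ± 0.34) among them. In whisker-minus 2 and 3 all 16 lay above every whisker-plus library, and in whisker-minus 1 only 2 did. Heat shock genes had 21 of 25 members above 0 (median 0.20, camera adjusted p = 3.89e-08), 4 passing adjusted over the list alone. With the block 9 rose, including Hsph1, Hspb1 (0.51 ± 0.06), Hsp90b1 (0.37 ± 0.05) and Xbp1 (0.43 ± 0.07), and 1 fell. Venous endothelial markers (10 of 14 above 0, camera adjusted p = 3.72e-05), NF-kB and inflammation genes (14 of 19, 0.000147), leukocyte adhesion genes (7 of 9, 0.0201) and glucocorticoid genes (16 of 23, 0.000255) overlap in members. The NF-kB list median of 0.14 became -0.079 without whisker-minus 3 (camera adjusted p = 0.0588) and -0.069 without whisker-plus 1. The call of leukocyte adhesion genes ended without either of these libraries (adjusted p = 0.146 and 0.0634) and with RLE or TMM scaling (0.0568 and 0.0534). With all 22 libraries in the fit leukocyte adhesion and glucocorticoid genes were not called (adjusted p = 0.0786 for both). Their rising genes with the block included Lcn2, Lrg1, Darc, Vcam1 (0.50 ± 0.10), Sele (1.14 ± 0.29), Osmr (0.75 ± 0.12), Il1r1 (0.47 ± 0.06), Map3k6 (0.47 ± 0.06) and Cebpd (0.48 ± 0.08), and adjusted over the list alone without the block 4, 4, 2 and 3 passed. Microglia markers lay above 0 in 14 of 14 (median 0.50, camera adjusted p = 1.68e-05), with no member passing. Blood markers did in 6 of 7 (0.42, 0.00897), but the globin genes Hbb-b1 and Hba-a1 that rose with the block have near-identical copies, so their values are uncertain. Retinoid and xenobiotic metabolism genes lay below 0 in 23 of 25 (median -0.25, camera adjusted p = 0.0044), 3 passing adjusted over the list alone, and Ephx1 (-0.35 ± 0.06), Gstt2 (-0.63 ± 0.12), Cyp2j9 (-0.83 ± 0.18) and Maob (-0.56 ± 0.12) fell with the block. ABC efflux genes lay below 0 in 12 of 13 (median -0.19, camera adjusted p = 0.00875), 2 passing adjusted over the list alone. Without whisker-minus 3 or whisker-plus 2 this call ended (adjusted p = 0.0876 and 0.0796), and that of blood markers ended without whisker-plus 2 (0.132), with no filter (0.0585) and with all 22 libraries (0.0575). Abcc6 (-0.46 ± 0.07), Abca2 (-0.48 ± 0.08) and Abca1 (-0.37 ± 0.06) fell with the block, while Abcb1a (-0.19 ± 0.11), Abcg2 (-0.08 ± 0.09), Abcc4 (-0.10 ± 0.11) and Abcb1b (-0.64 ± 0.35) did not pass. Clock output genes had 11 of 15 members below 0 and were not called (median -0.22, camera adjusted p = 0.693, and 0.461 with the block). With the block 4 of them fell, Dbp (-0.90 ± 0.19), Tef (-0.55 ± 0.11), Nr1d1 (-0.25 ± 0.07) and Per3 (-0.45 ± 0.10), and 1 rose, Cry1 (0.42 ± 0.10). Arntl (0.27 ± 0.07) rose with the block too, while Hlf (-0.22 ± 0.22), Per1 (-0.04 ± 0.24), Per2 (-0.16 ± 0.33), Nr1d2 (-0.03 ± 0.11), Ciart (0.07 ± 0.34, listed as Gm129) and Clock (0.01 ± 0.14) did not pass. The block also called oligodendrocyte precursor markers, 8 of 9 below 0 (camera adjusted p = 0.0461, and adjusted p = 0.646 with an estimated correlation).

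**Figure D3:**
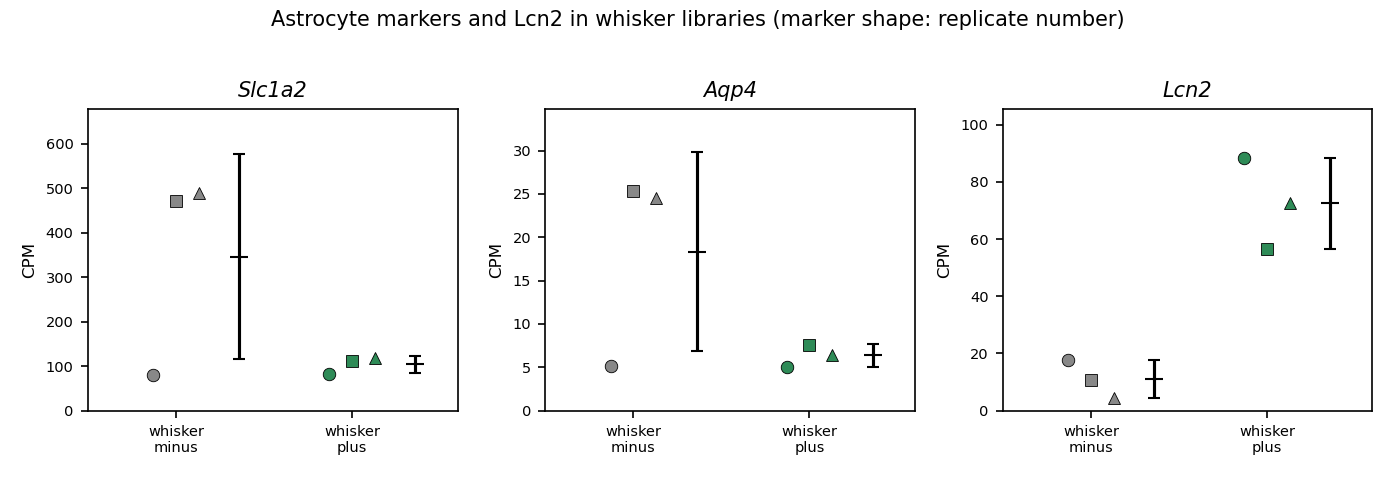
CPM per library of the astrocyte markers Slc1a2 and Aqp4 and of Lcn2 in the whisker groups, with points for libraries, marker shapes for replicate numbers and bars for mean ± SD. Lcn2 averaged 72.6 CPM in whisker-plus and 11 in whisker-minus libraries, and the astrocyte markers are spread across the whisker-minus libraries.

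Activation and whisker exploration were compared because both were meant to raise activity. In the fits with the replicate block 114 of 12458 genes tested in both changed in the same direction, 69 rising (Fisher's exact test, two-sided, p = 8.58e-71) and 45 falling (p = 2.17e-29), where independent lists would share 9.77. No gene changed in opposite directions, against 10.5 for independent lists. The Fisher tests treat genes as independent, which they are not. The shared genes with the smallest p-values were Mall (1.10 ± 0.12 and 1.09 ± 0.09), Fyn (0.84 ± 0.09 and 0.69 ± 0.07), the annexin Anxa2 (0.73 ± 0.07 and 0.51 ± 0.05), the cation channel Trpv4 (0.57 ± 0.07 and 0.60 ± 0.06), Adam15 (0.62 ± 0.08 and 0.47 ± 0.05), Schip1 (0.66 ± 0.09 and 0.62 ± 0.09) and the small GTPase Rhoc (0.72 ± 0.08 and 0.41 ± 0.06), which rose, and Ddc (-1.08 ± 0.09 and -0.61 ± 0.06), which fell. Across genes the log2 fold changes had a Pearson r of 0.34. Without the block the count was 0 with limma and 57 with DESeq2, while at an unadjusted p under 0.05 in both 471 genes had the same and 5 opposite directions. TMM scaling with the block gave 55 (40 rising, 15 falling), no filter 0, and leaving out a pair gave 0 (without whisker pair 3) to 134 (without whisker pair 1), with 2, 30, 5 and 33 without activation pairs 1, 2, 3 and 4. EdgeR with the block gave 42. Silencing and whisker exploration shared 14 genes of opposite and 10 of the same direction with the block, against 6.11 and 5.58 for independent lists.

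**Figure D4:**
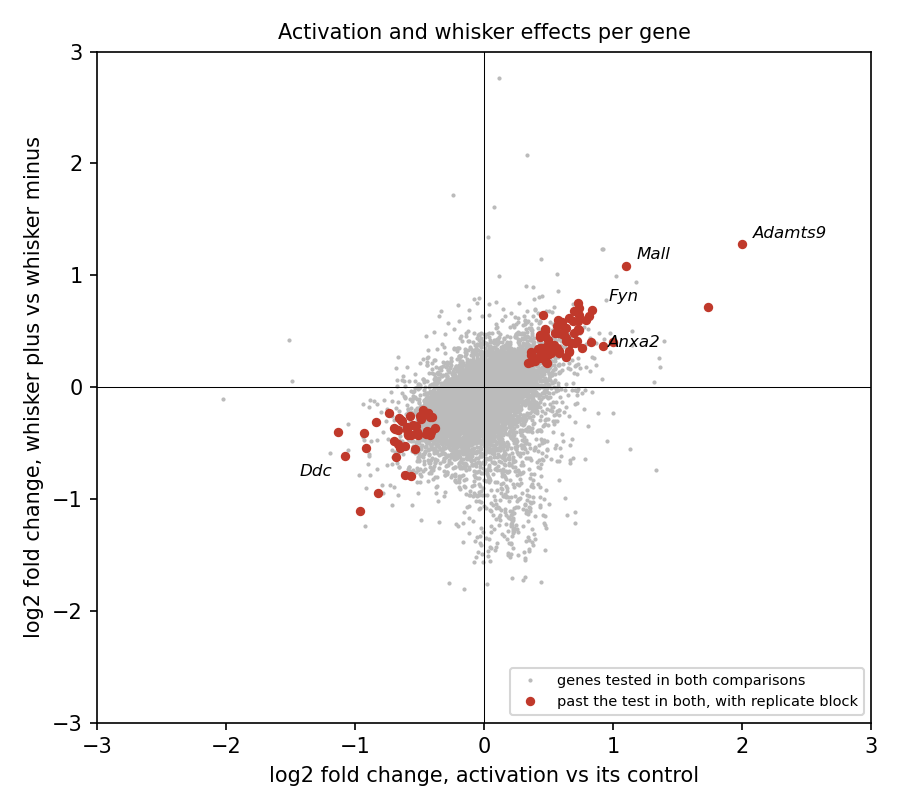
Log2 fold change after activation (x axis) against log2 fold change after whisker exploration (y axis) for 12458 genes, with 114 genes that passed in both with the replicate block in red. The red points lie in the lower left and upper right quadrants, 45 and 69 of them.

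List calls need a limit of their own. When the same libraries were grouped in other ways, the list test called as many lists or more in 34 of 35 groupings for activation, 32 of 35 for silencing, 5 of 10 for whisker and 89 of 100 for the difference of effects. Chance is therefore not excluded for the list calls of the DREADD comparisons, 10 groupings are too few to decide for whisker, and the counts of members above or below 0 describe these libraries.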

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

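Of the tests below, those on reads from another cell type, on scaling, on other groupings and on a silencing library set among the controls were chosen after the results were seen. In 390 tests of groups of 4, single libraries stood apart from the rest of their group 12 times, by a gap above Dixon's 95% critical value, and chance gives about 1 in 20. In the activation experiment these were Pdlim5 in activation 2 (231 CPM), Myof in activation 3 (32 CPM), Ccnd1 in activation 4 (198 CPM), Slc2a1 in activation control 1 (4458 CPM, against 6164 to 6414 in the other controls) and Tubb6 in activation control 2 (30.8 CPM). In activation control 1 the mean log2(CPM + 1) of glucocorticoid response genes (5.34) and of blood markers (5.10) also stood apart. In the silencing experiment they were the mean of organic anion and drug carriers in silencing 2 (6.22) and, in silencing control 2, Rasal2 (289.8 CPM), Abcc4 (1883 CPM), Slc2a1 (11784 CPM, against 5437 to 5995) and Spsb1 (54.6 CPM). The activation and silencing effects differed in 311 genes by the test of their difference. Of 100 groupings only the real grouping gave as many (highest other 118, or 35 among 100 that part every pair). This is the smallest share that 100 groupings can give, and it argues against chance. The groupings stand for no effect in either line, so they do not by themselves single out a difference between the effects.

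Glucocorticoid response genes were higher in the silencing libraries and also in silencing control 2. Positions run from the other controls at 0 to the silencing libraries at 1, and a mislabelled sample needs a position near 1. Over 1504 genes called without it, silencing control 2 lay at a median of 0.973 (95% bootstrap interval over genes, not libraries, 0.946 to 1.01). Beside left-out silencing libraries (86.9 to 90.6% of genes nearer the silencing mean) it reached at least 78.0% and the other controls 5.59 to 45.9%. By this share a silencing library and a control that shares much of the response cannot be told apart. For some genes it lay outside both groups. Angpt2 read 315 CPM, against 33.6 to 47.2 in the other controls and 24.9 to 60.1 in silencing libraries. Adamts9 read 164 CPM, against 13.7 to 20.1 and 16.6 to 42.1. A wrong label would not by itself give these values. They were picked after being seen and rest on this library alone, so they do not settle the label. Reads from another cell type stay open, since the glucocorticoid excess of 1.18 lay above the highest marker excess (0.818, microglia) by 0.361 with a 95% bootstrap interval over genes of -0.125 to 0.965, and smooth muscle (0.684), blood (0.579) and choroid plexus markers (0.544) had an excess too. It lay nearer the other controls for all 23 genes called with it as a control, Kdr, Urb2 and Plin2 included, but such a call favours genes of that kind, and 0 to 1 genes were called with a silencing library in its place against 0 to 13 with it, so neither decides on the label. The clock list median barely moved without silencing control 2 (0.49 and 0.50), but the members of that list go both ways. Its members Hlf, Tef and Per2 passed once that library was left out, as did Arntl, which belongs to another list. The median therefore decides nothing on the label. A stress response of the animal stays open as an untested biological explanation.

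More genes fell than rose in the whisker libraries with the replicate block, astrocyte markers among them. In whisker-minus 2 and 3 all 16 astrocyte markers lay above every whisker-plus library, as reads from astrocytes that passed the sort would give, while in whisker-minus 1 only 2 did. The 8 falling genes with the largest changes followed the same libraries. Over all 715 falling calls whisker-minus 1 lay at a median of 59.3% of the way from whisker-plus to the other whisker-minus libraries, with 307 genes under 50%. A call with the block favours genes that fall in pair 1 too, so this median does not decide on astrocyte reads. The sort for CD31 and against other markers is meant to leave out other cells, but how many astrocytes passed it was not tested. Scaling stays open as untested: falling genes made up 65.2% of calls without it and 42.6% with TMM, but TMM moved the median log2 fold change of all genes from -0.068 to -0.0061, which evens the directions whatever the cause, and a change in astrocytes or their contacts with vessels was not tested.

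Genes changed by activation and by whisker exploration moved in the same direction. Scaling is argued against, because with TMM 55 genes still changed in the same direction, with 4.67 for independent lists and 0 of opposite direction. Flips of the paired libraries cannot decide on chance here: the real one gave 114 genes and the highest other of the 64 gave 5, but only 1 other flip called enough genes in both experiments to reach 114. Reads from astrocytes are argued against as a direct source of the 69 shared genes that rose. In the whisker comparison the marker median lay below 0 in every pair (-1.92 to -0.016), so such reads would lower genes there. For the 45 that fell they stay open. The marker medians lay on opposite sides of 0 (0.18 after activation and -1.17 in the whisker comparison). Single pairs gave -0.38 to 0.71 after activation, so the sides are not beyond the spread. A response shared by raised activity in both experiments is one hypothesis, and handling or arousal of the treated mice is another that was not tested.

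Other groupings were run for the remaining counts. Of 35 groupings the real one alone gave 18 genes for activation (highest other 5) and 23 for silencing (highest other 1). Most of the 35 put libraries of a pair in the same group, and of the 8 that part every pair the highest other was 0 in both, which is too few for a share under 0.05. With the block, the 8 flips for activation (234 genes, highest other 7) and silencing (136, highest other 95) and the 4 for whisker (1097, highest other 0) are too few for a share under 0.05, as are the 10 groupings for whisker without the block (0 genes in each). The real grouping alone also gave 855 genes for the difference of effects with the block (of 100, highest other 324), which argues against chance there. It alone gave 6 opposite genes too (1 of 100, highest other 0), but only 4 of the others called enough genes in both comparisons to reach 6, so this decides nothing. Chance is not excluded for the correlations, with 31 of 100 reaching the negative r of activation and silencing (0.132, highest other 0.447) and 5 of 64 reaching the r of activation and whisker (0.336, highest other 0.466). For the lists it is not excluded either, with as many lists or more in 34 of 35 groupings for activation (5 lists, highest other 21), 32 of 35 for silencing (7, highest 15) and 89 of 100 for the difference (6, highest 19), or 65 of 100 with the block (9, highest 19). Too few groupings for a share under 0.05 were there for whisker lists (5 of 10, 10 lists, highest 17) and, with the block, for those of activation (7 of 8, 8 lists, highest 17), silencing (7 of 8, 9 lists, highest 14) and whisker (2 of 4, 11 lists, highest 14).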

How the results depend on the processing

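TMM scaling, edgeR, the fit of all 22 libraries for the difference of effects, the medians and calls of lists not called as fitted and every setting combined with the replicate block were chosen after seeing the data. Across RLE and TMM scaling, no filter, a pseudocount of 0.1, the block and the fit of all 22 libraries, no named gene and no median of a list called in that comparison changed its direction. For genes only the scalings and the pseudocount could show this. No filter, the block and the fit of all 22 libraries leave a gene's log2 fold change as it is. They can move a list median only by changing which members are tested, which the block does not do. Medians of other lists near 0 did, among those given that of endothelial markers in the whisker comparison (-0.03, and 0.04 with RLE or TMM). The cause of the changes below was not tested, except that a filter changes the number of tests and that leaving out libraries leaves fewer samples. The number of tests alone does not account for the 0 calls with the block and no filter. In the whisker comparison it rose from 12776 to 21673, while the smallest limma adjusted p with the block had been 0.00132. Genes let in without a filter also enter the mean-variance trend of the fit, and their part in this was not tested. Depth limits little here, since libraries hold 18387666 to 57673270 reads, but genes near 1 CPM rest on few reads.

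The 18 activation calls became 0 with RLE, TMM or no filter, 6 with a pseudocount of 0.1, 371 with DESeq2, 2 with edgeR, 234 with the replicate block, 243 with all 22 libraries and 0 to 8 with 1 library left out. The 23 silencing calls became 35 with TMM, 7 with no filter, 14 with a pseudocount of 0.1, 462 with DESeq2, 136 with the replicate block, 211 with all 22 libraries and 0 to 1504 with 1 library left out. The 0 whisker calls became 406 with DESeq2, 1097 with the replicate block and 0 to 352 with 1 library left out. The 311 genes that differed between the effects became 111 with no filter, 760 with DESeq2, 855 with the replicate block, 531 with all 22 libraries and 85 to 915 with 1 library left out. The 0 opposite calls of activation and silencing became 31 with DESeq2, 6 with the replicate block, 17 with all 22 libraries and 0 to 5 with 1 library left out, and the 0 same-direction calls of activation and whisker became 57 with DESeq2, 114 with the replicate block and 0 to 2 with 1 library left out.

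With an estimated correlation 0 of the 38 lists were called in each comparison, with or without the block, against 5 for activation, 7 for silencing, 10 for whisker and 6 for the difference. The activation lists became 4 with RLE or TMM, and the whisker lists 7 with all 22 libraries, 9 with no filter, 12 with RLE and 11 with TMM. With the replicate block they were 8, 9, 11 and 9, and the difference had 11 with no filter. With 1 library left out they were 3 to 15 (lowest without activation control 3, highest without activation 3), 5 to 11 (highest without silencing 2), 9 to 16 (highest without whisker-minus 1) and 5 to 11 (highest without activation 3). Of the 7 silencing lists 4 lay higher and 3 lower, against 2 and 6 of 8 with RLE or TMM. Of the lists, and of the genes whose value is given for a comparison, the block changed no call there beyond those given with the results.

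With the replicate block as the starting point, the 234 activation calls became 138 with TMM, 0 with no filter, 649 with DESeq2, 92 with edgeR and 5 (without pair 1) to 50 (without pair 4). The 136 silencing calls became 0 with no filter, 670 with DESeq2 and 0 (without pair 1, 3 or 4) to 2399 (without pair 2). The 1097 whisker calls became 0 with no filter and 1 to 2381, and the 855 of the difference 328 with no filter and 279 to 1392. The 6 opposite calls became 2 with TMM, 0 with no filter, 67 with DESeq2, 2 with edgeR and 0 to 64, and the 114 same-direction calls 55, 0, 256, 42 and 0 to 134. The 8 activation lists became 4 with TMM, 13 with no filter and 2 to 14, and the silencing, whisker and difference lists ran from 9 to 12, 12 to 14 and 6 to 12 without a pair.

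The log2 fold change of Nr1d2 after activation changed sign, from 0.03 to -0.039 with DESeq2 and -0.034 with edgeR. With 1 library left out, values that had not passed changed sign too. After activation they ran from -0.35 to 0.23 for Per1, -0.74 to 0.060 for Per2, -0.46 to 0.22 for Nr1d1, -0.22 to 0.31 for Nr1d2, -0.044 to 0.12 for Clock, -0.12 to 0.12 for Slc2a1, -0.012 to 0.16 for Mfsd2a and -0.13 to 0.26 for Fos. After silencing they ran from -0.24 to 0.0068 for Abcb1b and -0.017 to 0.10 for Clock. The glucocorticoid list median after activation ran from -0.0097 (without activation control 1) to 0.27, and the NF-kB list median of the whisker comparison from -0.079 (without whisker-minus 3) to 0.35.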

Other observations

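Some groups that were not called as fitted still describe the cells. Immediate early genes, which respond within minutes to many stimuli, had 21 of 31 members above 0 after activation (median log2 fold change 0.03, camera adjusted p = 0.63), 18 of 31 after silencing (0.08, adjusted p = 0.095) and 16 of 30 after whisker exploration (0.01, adjusted p = 0.14), with no member passing. Fos was high in every library, controls included, from 2401 CPM (whisker-minus 3) to 8963 CPM (silencing 1), which limits what its small changes can say. General endothelial markers lay around 0, with medians of -0.01 after activation, -0.10 after silencing and -0.03 after whisker exploration (0.04 with RLE or TMM scaling), and only Vwf and Kdr among them passed. The medians of all tested genes in these comparisons were -0.0072, -0.073 and -0.068. Hypoxia response genes had 16 of 22 members below 0 after silencing (median -0.31, camera adjusted p = 0.12), where Tpi1 fell, and 3 rose and 9 fell adjusted over the list alone. The list was called with RLE (adjusted p = 0.0254), TMM (0.0343) or no filter (0.0188), each at the preset correlation. With an estimated correlation no list was called as fitted. Arterial endothelial markers had 12 of 16 members below 0 after silencing (median -0.17, camera adjusted p = 0.095) and 11 of 16 in the whisker comparison (median -0.23, camera adjusted p = 0.14), with 7 and 5 falling adjusted over the list alone. After silencing they were called with RLE (adjusted p = 0.0364), TMM (0.0438), no filter (0.0223) or all 22 libraries (0.0462). These calls too used the preset correlation, and no list was called as fitted with an estimated correlation.

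The test below of silencing control 2 against the activation effect was set down before its result was seen. Silencing control 2 was also compared with the activation effect, to see whether it departs from the other controls in the way that excited neurons would give. Across 12667 genes its departure had an r of 0.169 with the activation effect, against 0.04, -0.24 and -0.04 for silencing controls 1, 3 and 4, and of 0.133 with the whisker effect. The value is the highest of the 4 but lies under the bound of 0.2 set for it, so the test decides nothing.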
